A study of Caenorhabditis elegans with 2 samples.

How the data were processed

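Total RNA from whole worms was sequenced in 2 libraries, 1 from N2 worms fed HT115 E. coli with an empty RNAi vector and 1 from N2 worms fed HT115 producing atp-2 double-stranded RNA. Per the labels' protocols the libraries were made with a strand-specific kit, and whether the strand was used in assigning fragments to genes was not given in the sources used here. Read processing used bcl2fastq 2.0, TopHat and Cufflinks with genome build WBcel235, per the submitters' processing notes; the versions of TopHat and Cufflinks, their settings and the annotation were not given in the sources used here.

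The authors deposited a table of all genes in FPKM, per the file headers, with 1 column per library, in which a gene without signal holds 1e-05. They also deposited, per the file headers, the ratio of the FPKM columns as a fold, the log2 of that ratio, and a p-value and q-value per gene from a test that is not named in the file. A second deposited table holds the genes the authors selected, with the same ratio, log2 and p-value columns. The ratio, log2, p and q columns were used only to describe the authors' selection and are named as theirs where printed. The table of all genes held 46245 gene rows, of which 45990 gene IDs were found in the Ensembl release 115 annotation, and 28647 had the same start and end there. A gene ID occurred in 2 rows, and 12036 further rows without a gene were left out. Coordinates are those of the deposited table. The floor of 1e-05 was read as 0, which 30398 rows held in the empty-vector library and 27396 in the atp-2 RNAi library. A value of 0 in such a table can be a failed estimate, so these genes are described as listed at 0 and get no fold.

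FPKM totals were 1049720 and 680167, and totals of FPKM times length in kilobases were 1526010 and 847669, so the 2 columns were not on a common total, and how the authors scaled the libraries to one another was not given in the sources used here. Counts of fragments were not used here. The smallest values of 22 genes near the detection limit were compared to estimate relative depth. Of these, 17 lay within 0.1 log2 of the median ratio of -0.57, so 1 fragment in the atp-2 RNAi library was worth 0.675 of 1 in the empty-vector library. With this unit 21.5% of 1730 low values and 22.8% of 1357 were whole numbers of fragments within 0.1, about the share chance gives, so whole counts could not be recovered and no count test was run. The total of FPKM times length in this unit was lower in the atp-2 RNAi library although 1 FPKM there stood for more fragments, so which library was deeper was not established, and no counting intervals were computed.

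Each gene's ratio was taken as log2 of (FPKM + 1) under atp-2 RNAi over (FPKM + 1) with empty vector. A gene was counted as higher or lower at an absolute log2 ratio of at least 1 if it had at least 1 FPKM in a library; this is a rule of size and not a test. With 1 library per group no p-values were computed. The median log2 ratio of each gene list was placed among the medians of 10000 random lists of the same size, matched on mean FPKM over both libraries in 20 bins, for lists with at least 5 measured members. A list was described as standing apart outside the central 95%, where 5% of lists of genes drawn at random would fall. This describes these libraries only.

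The groups, the size rule, the pseudocount, 33 gene lists, 8 cell type lists, the alternatives and the rule for named genes were fixed before the data were examined. The lists were mtDNA-encoded subunits, ATP synthase, respiratory complexes I to IV, mitochondrial ribosome, mitochondrial unfolded protein response, mitochondrial fusion, fission and mitophagy, tricarboxylic acid and glyoxylate cycles, glycolysis, fatty acid synthesis and desaturation, lipases and fatty acid oxidation, cytochrome P450, UDP-glucuronosyltransferases, glutathione S-transferases, oxidative stress enzymes, cytosolic heat shock, endoplasmic reticulum unfolded protein response, hypoxia and hydrogen sulfide, C-type lectins, antimicrobial effectors, pals genes, DAF-16 targets, lysosome and autophagy, proteasome, cytosolic ribosome, serotonin and other monoamines, glutamate signalling and learning, FMRFamide-like peptides, neuropeptide-like proteins, insulin-like peptides, vitellogenins, cuticle collagens, moulting, and DNA replication and cell division. The cell type lists were oocyte and germline, sperm, embryo, intestine, body wall muscle, pharynx, neurons, and hypodermis and seam. They hold 1609 genes, 19 of them in several lists, and were written from general knowledge of the worm, so members are also used in other cells. The named genes were atp-2, the 12 genes with the highest and the 12 with the lowest log2 ratio among those with at least 5 FPKM in the higher library, at most 2 per name stem, and for each list up to 2 highest members, 2 lowest members and the most abundant member. Genes named outside this rule are said to be chosen after their values were seen.

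The alternatives were pseudocounts of 0.1 and 5, no filter, filters of 10 FPKM in a library and of 1 FPKM in both, equal FPKM totals, equal upper quartiles, a median ratio of 1 over genes of at least 10 FPKM, protein-coding genes only, unmatched random lists and list members of at least 10 FPKM. Equal totals of FPKM times length, X-linked genes only, and genes outside the germline, stage and cell division lists were added after the data were seen. The size rule and the list percentiles were tested on simulated data made from 9379 genes of this comparison with a noise of 0.25 log2 per library. The rule called 100% of genes made 4-fold higher, 99% of those made 4-fold lower and 0.294% of unchanged genes. Of 200 unchanged lists of 20 genes, 5% fell outside the central 95%, and 99.5% of lists raised by 0.5 log2 lay above it. The simulated genes had a mean of at least 5 FPKM and independent noise of an assumed size, and nearly all were unchanged. In the real libraries most genes passed 2-fold and members of a list can move together. These rates show that the calculation works and are not error rates for the real libraries. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.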

Results

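The data were 1 RNA-seq library from whole N2 worms, the wild-type laboratory strain of Caenorhabditis elegans, fed HT115 E. coli with an empty RNAi vector, and 1 library from N2 worms fed HT115 producing double-stranded RNA against atp-2. The gene atp-2 encodes the beta subunit of the mitochondrial ATP synthase, and feeding worms such bacteria lowers the matching mRNA. The worms' stage at harvest was not given in the sources used here. The study asked which pathways accompany loss of this subunit and could bear on an aversive memory. Levels are FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) for the empty-vector library first and the atp-2 RNAi library second. Ratios are atp-2 RNAi over empty vector, on the log2(FPKM + 1) scale, which understates differences of low genes. With 1 library per group there was no replicate error, so "higher" and "lower" describe these libraries and not the conditions. The FPKM values of all genes summed to 1049720 in the empty-vector library and 680167 in the atp-2 RNAi library, and 10731 and 13452 genes reached 1 FPKM. The number of fragments behind these values, and so the counting error, is unknown.

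The targeted gene was lower in the atp-2 RNAi library. The level of atp-2 (WBGene00000229, chromosome III, positions 5228417 to 5230544, plus strand, build WBcel235) was 1348 FPKM in the empty-vector library and 116 FPKM in the atp-2 RNAi library, a log2 ratio of -3.53 and an 11.5-fold lower level. The other scalings between the libraries put this log2 ratio between -2.90 and -2.33. The value covers the whole gene, and the part matched by the double-stranded RNA was not given in the sources used here. The authors' deposited table gives atp-2 p = 0.06255 and q = 0.430 in a test on these 2 libraries, which compares the libraries and not the conditions.

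Among the 12 genes with the highest ratios was tbb-6, a beta-tubulin gene used as a reporter of mitochondrial dysfunction, at 1.56 and 330.1 FPKM (129-fold higher, chromosome V, positions 12261804 to 12263368). Other genes at the top of the ranking were the saposin-like genes spp-9 (0.178 and 261 FPKM) and spp-21 (0.724 and 245 FPKM), the Rab-family GTPase gene rab-11.2 (0.223 and 246 FPKM), and the cytochrome P450 genes cyp-13A8 (0.326 and 166 FPKM) and cyp-14A4 (0.311 and 134 FPKM). The sequence-named genes B0205.14 (0.437 and 299 FPKM), Y37H2A.14 (2.51 and 480.1 FPKM) and F22B3.7 (0.131 and 113 FPKM) belonged there too. C02E7.6, C02E7.7 and the sperm gene nspd-1 were listed at 0 in the empty-vector library and at 257, 106 and 89.2 FPKM in the other. At the bottom of the ranking stood the yolk protein genes vit-3 (1788 and 15.7 FPKM, 107-fold lower) and vit-1 (2291 and 21.3 FPKM, 103-fold lower). They were followed by the lysozyme gene ilys-5 (1902 and 19.4 FPKM, 93.3-fold lower), the octopamine synthesis gene tbh-1 (324 and 9.08 FPKM, 32.3-fold lower) and the peroxidase gene skpo-1 (313 and 10.2 FPKM, 27.9-fold lower). The remaining 7 of the 12 lowest were short non-coding genes, such as K03E5.9 (272 FPKM and listed at 0) and T23G11.12 (95.3 and 0.142 FPKM), whose FPKM values are uncertain because few fragments fit their length.

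Of 13976 genes with at least 1 FPKM in a library, 4697 were at least 2-fold higher under atp-2 RNAi, 4787 were at least 2-fold lower and 4492 lay between. At least 8-fold differences were more often upward, with 703 genes higher and 265 lower. The direction depended on abundance: among 6202 genes with at least 10 FPKM in both libraries, 546 were higher and 3487 lower, with a median log2 ratio of -1.17, while the median over all genes was -0.02. It also depended on the scaling between the libraries. Giving both libraries the same FPKM total moved the median of all genes by 0.53, the same total of FPKM times length by 0.72, the same upper quartile by 0.93, and a median ratio of 1 for genes of at least 10 FPKM by 1.01. Genes higher made up 49.5% of those past 2-fold as deposited, and 67.7%, 74.7%, 82.5% and 85.2% under those scalings, against 30.8% when only genes reaching 10 FPKM were kept. The 4 scalings are named below in the order FPKM total, FPKM times length, upper quartile and median ratio. Counts of list members past 2-fold are given as deposited, and since these scalings raise every atp-2 RNAi value, they add higher and remove lower genes.

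**Figure D1:**
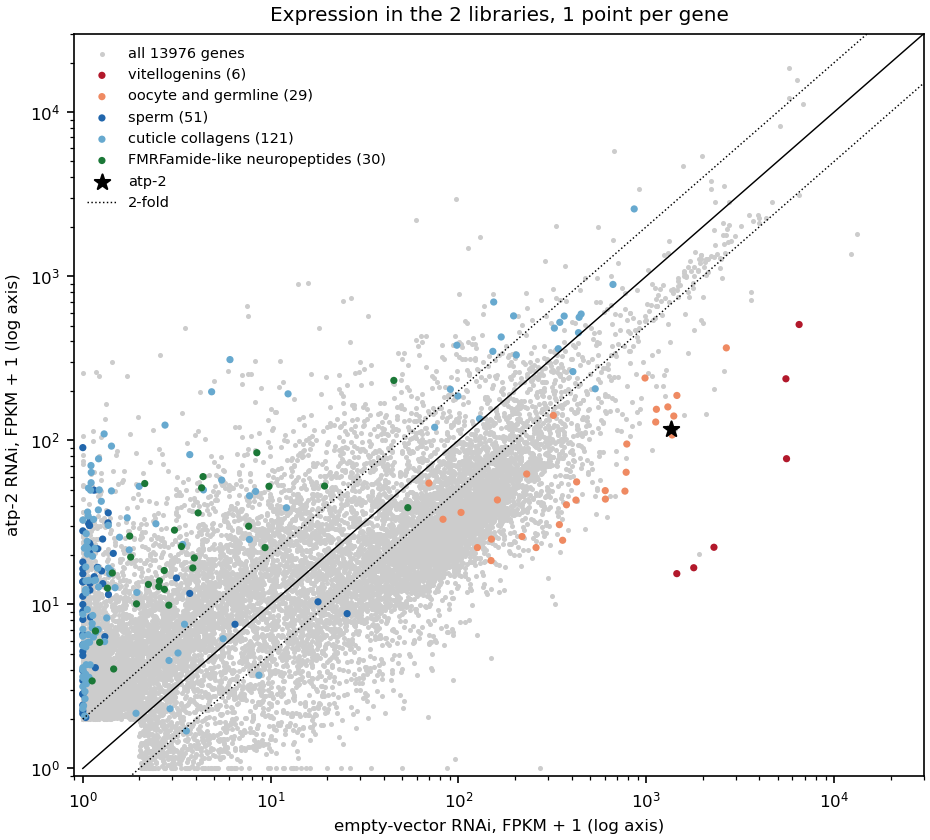
Expression of 13976 genes, with FPKM + 1 in the empty-vector library on the horizontal log axis and FPKM + 1 in the atp-2 RNAi library on the vertical log axis; each point is 1 gene, the solid line marks equal values and the dotted lines 2-fold differences. The 6 vitellogenin genes and 28 of 29 oocyte and germline genes lie below the lower dotted line, and 47 of 51 sperm genes, 100 of 121 collagen genes and 29 of 30 FMRFamide-like neuropeptide genes lie above the upper one.

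Genes of oocytes, yolk and dividing cells were lower together in the atp-2 RNAi library. All 6 vitellogenin genes, which encode yolk proteins, were at least 2-fold lower, and their summed level went from 23153 FPKM to 869.8 FPKM, with vit-2 at 6509 and 506 FPKM and vit-6 at 5536 and 236 FPKM. Of 29 measured oocyte and germline genes, 28 were lower, among them the yolk receptor gene rme-2 (769 and 48.0 FPKM), the eggshell chitin synthase gene chs-1 (358 and 23.6 FPKM) and the RNA helicase gene cgh-1 (2666 and 365 FPKM). The exception was the meiotic chromosome pairing gene syp-1 (68.6 and 53.8 FPKM). All 35 DNA replication and cell division genes were lower, among them the cyclin gene cyb-2.2 (534 and 44.5 FPKM), the ribonucleotide reductase gene rnr-2 (566 and 55.9 FPKM) and the tubulin gene tbb-2 (1302 and 511 FPKM). Of 4 measured embryo genes, 3 were lower, including cey-2 (2072 and 144 FPKM), and sdz-28 was higher (0.0612 and 1.41 FPKM). The list medians were -6.37 for vitellogenins, -3.03 for oocyte and germline, -2.33 for cell division and -2.40 for embryo. The first 3 lay below the central 95% of 10000 random lists matched on mean expression (-2.12 to 0.41, -1.66 to -0.58 and -1.71 to -0.85), and the embryo list was too short for a percentile. With no filter the embryo list had 15 members, most under 1 FPKM, and a median of -0.0326 below its random range. These medians stayed negative under every scaling, although the number of 2-fold lower cell division genes went from 35 to 23 and that of oocyte and germline genes from 28 to 22 under the scaling with a median ratio of 1. Vitellogenin genes share much sequence, so the division of fragments among vit-3, vit-4 and vit-5 is uncertain.

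Sperm and cuticle genes were higher together. Of 51 measured sperm genes, 47 were at least 2-fold higher, with a list median of 3.48 (random lists 0.31 to 1.26). The 29 measured genes of the major sperm protein family had a median of 0.0881 FPKM in the empty-vector library and 12.7 FPKM in the atp-2 RNAi library, and all 29 were higher, though their near-identical sequences make single values uncertain. The sperm gene sss-1 stood at 0.147 and 48.6 FPKM, while spe-44, a regulator of the sperm programme, stood at 24.5 and 7.78 FPKM. Of 121 measured cuticle collagen genes, 100 were higher and 3 lower, with a median of 2.62 (random lists -0.18 to 0.77). Examples were dpy-5 (0.299 and 108 FPKM, 84.2-fold higher), col-147 (0.421 and 91.1 FPKM) and the most abundant, col-140 (861 and 2567 FPKM), against col-101 (534 and 205 FPKM). Moulting and cuticle turnover genes were higher in 13 of 22 and lower in 1, with a median of 1.91 (random lists -0.03 to 1.59). They included grl-21 (0.310 and 28.5 FPKM), wrt-10 (0.127 and 12.55 FPKM) and, in the other direction, the moulting regulator nhr-23 (60.7 and 23.7 FPKM). The moulting median fell inside the random range with a pseudocount of 5 (0.753) and among genes reaching 1 FPKM in both libraries (0.786). The sperm and collagen medians stood apart from their random lists under every scaling, and among genes reaching 10 FPKM in a library they were 3.61 and 3.99 for collagens and sperm. Requiring 1 FPKM in both libraries left 5 of the 51 sperm genes, since most were near 0 with empty vector, and their median of 0.226 lay inside the random range.

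Neuropeptide genes were higher almost as a class. Of 30 measured FMRFamide-like peptide genes, 29 were at least 2-fold higher, with a median of 2.43 (random lists -0.72 to 1.18), led by flp-15 (1.14 and 53.5 FPKM, 25.5-fold higher) and flp-5 (0.777 and 25.06 FPKM). The most abundant was flp-28 (44.3 and 230.5 FPKM), and flp-6 stood at 52.7 and 37.8 FPKM. Of 49 measured genes of the other neuropeptide class, the neuropeptide-like proteins, 41 were higher and 1 lower, with a median of 2.27 (random lists -0.44 to 1.01). They included nlp-20 (5.78 and 119.2 FPKM) and nlp-34 (0.691 and 30.7 FPKM), and the lower gene was nlp-56 (14.1 and 4.42 FPKM). This list took every gene of that name, and some of them, such as nlp-34, are also in the antimicrobial list. Neuron marker genes were higher in 16 of 20 and lower in 1, with a median of 1.66 (random lists -0.87 to 1.27). The dense-core vesicle genes ida-1 (2.14 and 34.3 FPKM) and sbt-1 (8.87 and 90.6 FPKM) led them, and the synaptic vesicle gene snb-1 stood at 251 and 286 FPKM. Insulin-like peptide genes were higher in 17 of 23 and lower in 1, with ins-27 at 23.6 and 146 FPKM and ins-34 at 8.70 and 1.11 FPKM, and a median of 1.5001 at the edge of the random range (0.45 to 1.5031), above which it lay with equal upper quartiles and with a median ratio of 1.

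Among transmitter genes, the steepest differences were downward, in RNA of whole worms that does not show which cells they arose in. The tyramine and octopamine synthesis genes tdc-1 (163 and 16.3 FPKM, 9.46-fold lower) and tbh-1 were lower, while the other serotonin and monoamine genes included the monoamine oxidase gene amx-2 (3.14 and 10.99 FPKM) and the transporter gene snf-3 (4.33 and 11.9 FPKM). Of the 20 measured genes of this list, 5 were higher and 5 lower, with a median of 0.54 inside the random range (0.10 to 1.35) that was -0.812 among genes reaching 10 FPKM. Under the 4 other scalings 9, 9, 11 and 11 were higher and 2 lower in each. Glutamate signalling and learning genes were higher in 9 of 20 and lower in 1, with a median of 0.86 inside the random range (-0.61 to 1.29), and in 11, 13, 13 and 14 under the 4 other scalings. Among them were the innate immune and neuronal adaptor gene tir-1 (5.05 and 37.3 FPKM), the glutamate-gated chloride channel gene glc-1 (5.51 and 19.998 FPKM), and hen-1, a secreted protein gene needed for associative learning (2.08 and 0.0474 FPKM).

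As deposited, most nuclear genes of the respiratory chain lay within 2-fold of their empty-vector level. Of 16 measured genes of the ATP synthase list, which leaves out atp-2, 2 were higher and 2 lower, with a median of -0.14. This list holds mai-1 and mai-2, which are related to an inhibitor of the enzyme and are not subunits of it. Of 34 genes of complexes I to IV, 2 were higher and 2 lower, with a median of -0.20. Both medians lay above the ranges of random lists of equal abundance (-1.76 to -0.29 and -1.64 to -0.69), and both turned positive under each of the 4 other scalings, with 4, 5, 8 and 8 ATP synthase genes and 5, 6, 14 and 16 genes of complexes I to IV higher. The ATP synthase list then lay inside the random range (percentiles 96.0, 95.5, 93.4 and 92.2), while complexes I to IV stayed above it. Against random lists not matched on expression, neither list stood apart (percentiles 43.5 and 38.4). The inhibitor-related gene mai-1 (13.6 and 78.1 FPKM) and the ATP synthase gene asb-2 (112 and 249 FPKM) were higher. The position of mai-1 overlaps that of gpd-2 on the same strand, which was also higher (94.7 and 430.6 FPKM). The ATP synthase genes asb-1 (440.2 and 76.5 FPKM) and asg-1 (197 and 47.5 FPKM) were lower. The 12 protein genes of mitochondrial DNA included 5 that were higher and none that was 2-fold lower, with ctc-3, a cytochrome oxidase subunit gene, at 5744 and 18654 FPKM. Their median was 0.75 (random lists -1.80 to -0.01), with 8, 10, 11 and 11 genes higher under the 4 other scalings, and their share of all FPKM was 4.02% and 12.7%. Against unmatched lists this median did not stand apart (percentile 80.7). Mitochondrial ribosome genes were lower in 34 of 66 and higher in 0, with a median of -1.01 just above the random range (-1.57 to -1.02), and this median became positive with equal upper quartiles and with a median ratio of 1. Under the 4 other scalings 9, 3, 0 and 0 of these genes were lower and 1, 1, 3 and 4 higher, and the list lay inside the random range (percentiles 96.1, 94.7, 93.2 and 92.3), and it lay below unmatched lists (0.35). Tricarboxylic acid and glyoxylate cycle genes were higher in 2 of 19 and lower in 3, with a median of -0.29 (random lists -1.78 to -0.51) that also turned positive under the 4 other scalings, with 6, 8, 8 and 8 genes higher. Its place above the random range was lost under all 4 (percentiles 97.0, 96.4, 95.6 and 94.6) and against unmatched lists (36.9). The glyoxylate gene icl-1 (30.6 and 166 FPKM) and the gluconeogenesis gene pck-1 (44.5 and 180.1 FPKM) were the higher members, and the succinyl-CoA synthetase gene sucg-1 was lower (232 and 37.3 FPKM).

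The genes of the mitochondrial unfolded protein response, a chaperone and protease programme, moved both ways as deposited. Of 16 genes, 4 were higher and 3 lower, with a median of -0.23 inside the random range (-1.67 to -0.03). Under the 4 other scalings the median was positive, with 4, 5, 7 and 8 genes higher and 1, 0, 0 and 0 lower, and stayed inside the random range. The chaperone genes differed, with hsp-6 at 619 and 632 FPKM and hsp-60 at 627 and 185 FPKM, while the import gene timm-23 stood at 102 and 387 FPKM. The 4 other scalings raise each of these ratios, so the near-equal levels of hsp-6 hold only as deposited. Among 13 genes of mitochondrial fusion, fission and mitophagy, 2 were higher, including the mitophagy gene dct-1 (11.3 and 97.7 FPKM), and 4 were lower, including the parkin gene pdr-1 (92.2 and 25.7 FPKM). Their median of -0.63 lay inside the random range (-1.79 to -0.14) and was positive under 3 of the 4 other scalings, with 2, 0, 0 and 0 genes lower.

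**Figure D2:**
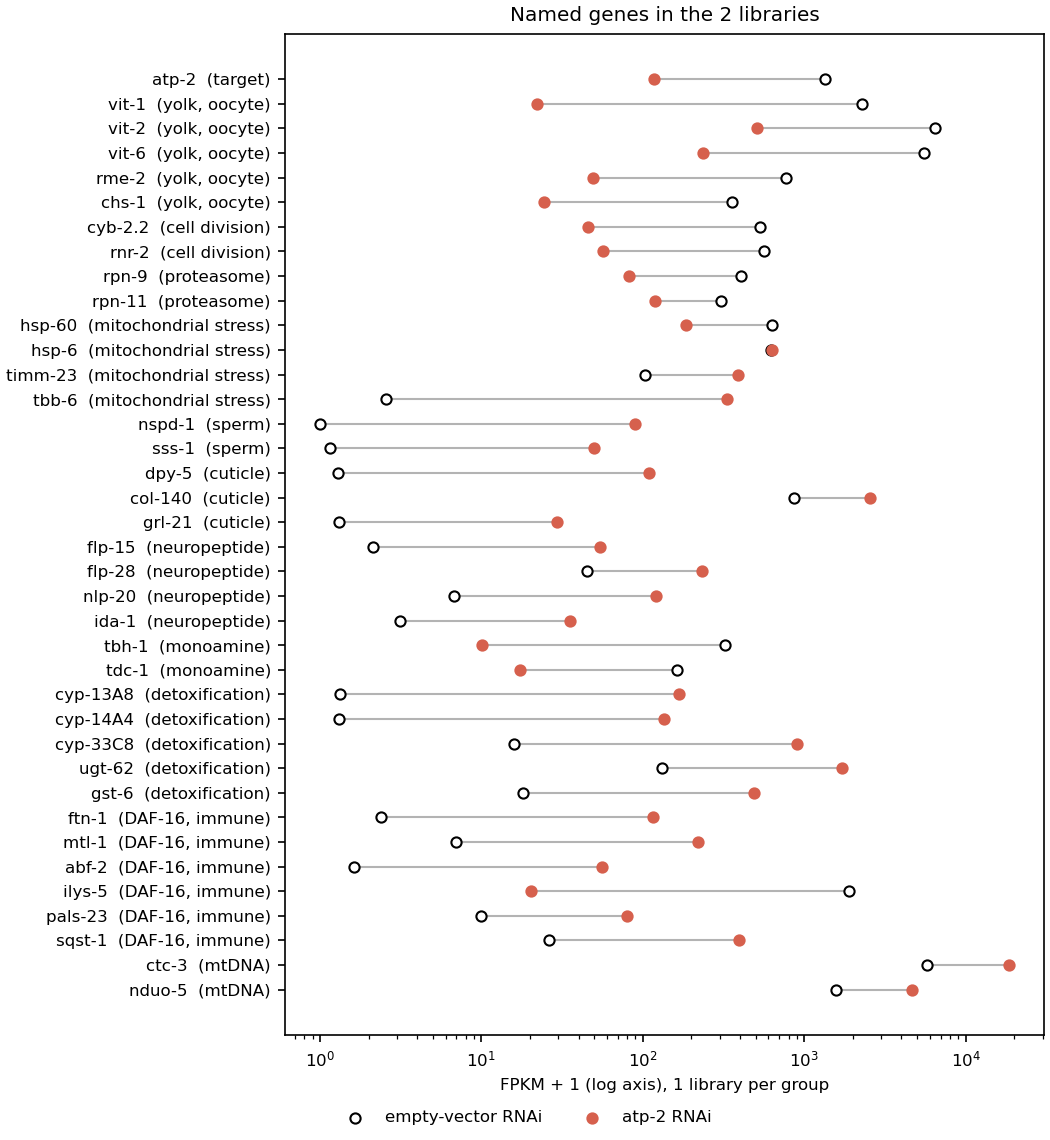
Levels of named genes, grouped by function, with FPKM + 1 on a horizontal log axis; open circles are the empty-vector library and filled circles the atp-2 RNAi library, 1 library each. atp-2, vit-1 and tbh-1 sit to the left under atp-2 RNAi, tbb-6, cyp-13A8 and flp-15 to the right, and the 2 circles of hsp-6 nearly coincide as deposited.

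Among detoxification and stress lists, cytochrome P450 and DAF-16 target genes stood apart in every setting. Cytochrome P450 genes, which oxidise foreign and endogenous compounds, were higher in 40 of 62 and lower in 11, with a median of 1.395 (random lists -0.11 to 1.05). The most abundant, cyp-33C8, stood at 14.8 and 907 FPKM (57.4-fold higher), and cyp-25A1 at 32.0 and 1.03 FPKM. UDP-glucuronosyltransferase genes, which conjugate such compounds, were higher in 26 of 54 and lower in 5, with a median of 0.96 (random lists -0.60 to 0.88), among them ugt-62 (130 and 1724 FPKM) and ugt-18 (0.116 and 49.6 FPKM), but without the FPKM filter the median was 0.557 and inside the random range, and 35, 37, 41 and 41 genes were higher under the 4 other scalings. Glutathione S-transferase genes were higher in 16 of 34 and lower in 3, with a median of 0.82 inside the random range (-0.35 to 1.18), led by gst-6 (17.02 and 485 FPKM), and above it among genes reaching 10 FPKM; 21, 22, 24 and 24 were higher under the 4 other scalings. Of 13 genes activated by DAF-16, the transcription factor of insulin signalling, 11 were higher and none was 2-fold lower, with a median of 2.40 (random lists -1.55 to 0.99). They included the ferritin gene ftn-1 (1.38 and 115.05 FPKM, 48.9-fold higher) and dod-6 (6.53 and 251 FPKM). Oxidative stress enzyme genes were higher in 4 of 18 and lower in 5, with the metallothionein gene mtl-1 at 6.01 and 219 FPKM, its relative mtl-2 at 127 and 24.3 FPKM, and a median of -0.23 inside the random range (-1.65 to -0.07). Under the 4 other scalings it was positive, with 7, 7, 8 and 8 genes higher and 1 lower in each.

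Immune and other stress lists differed from one another. Of 20 measured pals genes, which belong to the intracellular pathogen response, 16 were higher and none was 2-fold lower, with a median of 2.29 (random lists -0.19 to 1.55). pals-35 stood at 3.17 and 54.8 FPKM, while the regulators pals-22 (3.36 and 3.25 FPKM) and pals-25 (5.88 and 5.58 FPKM) differed little. Without the filter of 1 FPKM the pals median was 0.605 and lay inside the random range. Antimicrobial effector and infection response genes were higher in 14 of 36 and lower in 6, with a median of 0.76 (random lists -0.95 to 0.71) that did not stand apart from unmatched lists (percentile 92.2), and 22, 23, 23 and 24 were higher and 4, 3, 3 and 3 lower under the 4 other scalings. Among these the defensin-like gene abf-2 stood at 0.616 and 54.6 FPKM and the lysozyme gene lys-4 at 210.1 and 18.8 FPKM, beside ilys-5. C-type lectin genes were higher in 41 of 86 and lower in 18, with a median of 0.96 inside the random range (-0.03 to 0.99), with clec-47 at 112 and 1476 FPKM and clec-87 at 1424 and 116 FPKM. This median lay above the random range with equal FPKM totals and among genes reaching 10 FPKM, but for C-type lectins with no filter it was 0.0855, low in the range (percentile 6.67), and among genes reaching 1 FPKM in both libraries -0.0605. Under the 4 other scalings 50, 51, 52 and 53 were higher and 11, 10, 8 and 8 lower. Cytosolic heat shock genes were higher in 7 of 14 and lower in 4, with a median of 1.11 (random lists -1.41 to 0.72). Small members such as hsp-12.3 (2.19 and 58.3 FPKM) were higher and hsp-110 (510.0 and 111 FPKM) was lower, and among members reaching 10 FPKM the median was -0.69 and inside the random range, as it also lay without the filter and with a median ratio of 1, and 1, 1, 1 and 0 genes were lower under the 4 other scalings. Hypoxia and hydrogen sulfide response genes were higher in 5 of 11 and lower in 0, with nhr-57 at 3.04 and 54.1 FPKM, cysl-2 at 16.39 and 99.1 FPKM, and a median of 0.93 inside the random range (-1.47 to 1.35), and 6, 8, 8 and 8 were higher under the 4 other scalings. Endoplasmic reticulum unfolded protein response genes were lower in 12 of 17 and higher in 0, including the BiP chaperone gene hsp-4 (458 and 88.2 FPKM). Their median of -1.19 lay inside the random range (-1.67 to -0.13) and was 0.0033 with a median ratio of 1, and 3, 1, 1 and 1 of the 17 genes were lower under the 4 other scalings.

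Genes of the proteasome, which degrades tagged proteins, were lower as deposited in 33 of 33 cases, with a median of -1.86 below the random range (-1.61 to -0.58). The range of members was narrow, from rpn-11 (305 and 118 FPKM) to rpn-9 (406 and 81.1 FPKM). The number 2-fold lower was 29 with equal FPKM totals, 17 with equal totals of FPKM times length, 5 with equal upper quartiles and 1 with a median ratio of 1, while the median stayed below the random range in each of them. Cytosolic ribosome genes were higher in 2 of 77 and lower in 10, with rpl-11.2 at 121 and 382 FPKM and rpl-11.1 at 1953 and 542 FPKM. Their median of -0.76 lay inside the random range (-1.16 to -0.60) and became positive under 3 of the 4 other scalings, with 1, 0, 0 and 0 genes lower, but lay below unmatched lists (percentile 2.27). Lysosome and autophagy genes were higher in 5 of 52 and lower in 14, with a median of -0.37 above the random range (-1.46 to -0.63) that turned positive under the 4 other scalings, with 6, 4, 4 and 2 genes lower and 8, 11, 17 and 21 higher. It stayed above the random range under these scalings but not against unmatched lists (percentile 24.4). The autophagy adaptor gene sqst-1 (25.4 and 393 FPKM, 14.9-fold higher) and the cathepsin gene cpl-1 (1131 and 214 FPKM) went opposite ways.

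Among genes of central and lipid metabolism the direction differed gene by gene. Glycolysis genes were higher in 5 of 19 and lower in 6, with a median of -0.57 inside the random range (-1.73 to -0.37). It was positive under the 4 other scalings, with 5, 5, 6 and 6 genes higher and 3, 3, 2 and 2 lower. The aldolase gene aldo-1 stood at 32.2 and 569 FPKM, and the glyceraldehyde-phosphate dehydrogenase gene gpd-1 at 308 and 21.8 FPKM. Fatty acid synthesis and desaturation genes were higher in 1 of 15, the desaturase gene fat-3 (58.4 and 143 FPKM), and lower in 5, among them the desaturase gene fat-7 (15.9 and 0.863 FPKM). Their median of -0.51 lay inside the random range (-1.74 to -0.06) and was positive under the 4 other scalings, with 3, 4, 5 and 6 genes higher. Lipase and fatty acid oxidation genes were higher in 3 of 21, including the acyl-CoA synthetase gene acs-2 (22.5 and 119.5 FPKM), and lower in 13, including the acyl-CoA dehydrogenase genes acdh-1 (1672 and 338 FPKM) and acdh-2 (39.7 and 1.17 FPKM). Their median was -1.30, inside the random range (-1.41 to 0.64), and below it with a median ratio of 1 and without the filter; 6, 6, 7 and 7 genes were higher and 7, 5, 4 and 4 lower under the 4 other scalings.

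Lists of somatic tissue markers differed. Body wall muscle genes were higher in 10 of 16, none 2-fold lower, with a median of 1.14 (random lists -1.53 to 0.35), with the myosin gene myo-3 at 6.40 and 43.96 FPKM. Pharynx genes were higher in 8 of 10, with a median of 1.92 inside the random range (-0.08 to 2.097), including the regulator pha-4 (1.18 and 11.3 FPKM), and with no filter a median of 0.620 (percentile 59.3). Hypodermis and seam genes were higher in 9 of 15 and lower in 2, with a median of 1.17 inside the random range (-1.27 to 1.22) as deposited and above it under the 4 other scalings, but -0.593 among genes reaching 1 FPKM in both libraries, with the cuticle collagen gene rol-6 at 0.0427 and 21.6 FPKM and ptr-2 at 337 and 37.7 FPKM. Intestine genes were higher in 3 of 16 and lower in 2, with the regulator elt-2 at 3.40 and 27.7 FPKM, the protease gene asp-1 at 918 and 3414 FPKM, and a median of 0.29 (random lists -1.66 to -0.10), and 7, 10, 10 and 10 were higher under the 4 other scalings. Against unmatched lists the muscle and intestine medians did not stand apart (percentiles 95.9 and 63.1). Of the 40 lists long enough for a percentile, 20 lay above and 4 below the central 95% of their random lists. Genes drawn at random would give 2 such lists, but members of a real list can move together. This tally depends on the matching: against unmatched lists 13 lay above and 7 below, with the insulin, C-type lectin and pharynx lists moving above and the lipase, cytosolic ribosome and mitochondrial ribosome lists moving below.

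**Figure D3:**
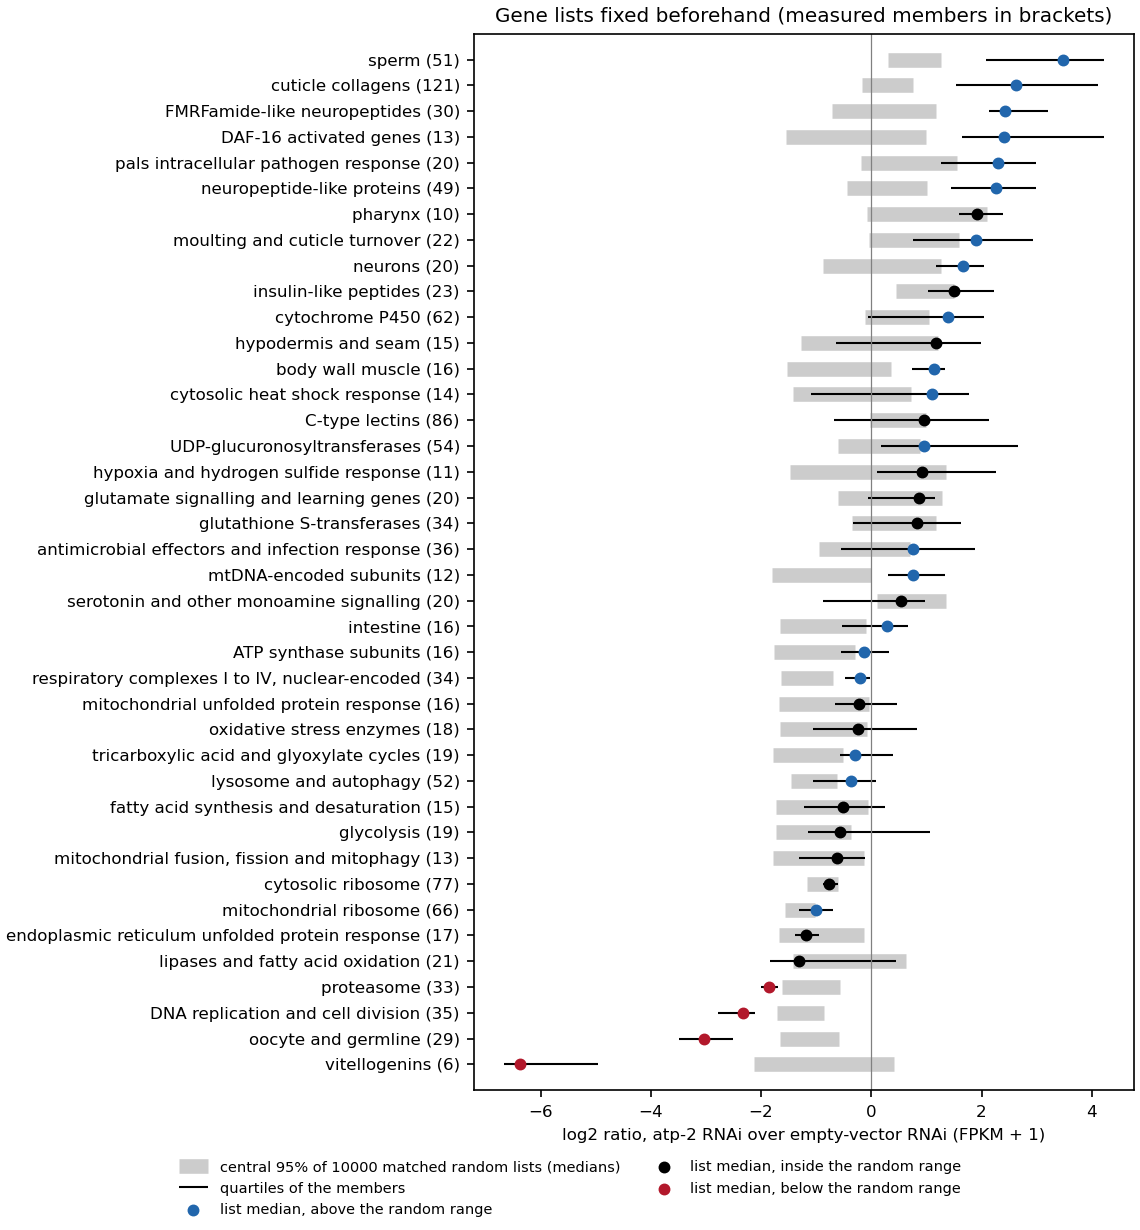
Median log2 ratio (atp-2 RNAi over empty vector, FPKM + 1) of 40 gene lists on the horizontal axis, 1 list per line with its measured members in brackets; dots are medians, thin lines the members' quartiles and grey bars the central 95% of the medians of 10000 matched random lists. Vitellogenins lie furthest left at -6.37 and sperm genes furthest right at 3.48; the medians of ATP synthase and complexes I to IV, left of 0 here, turned positive under the other scalings.

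The authors' deposited table of selected genes held 1772 genes, 1593 higher and 179 lower under atp-2 RNAi, which matched those with p of at most 0.05, a 2-fold ratio and at least 0.3 FPKM in a library. Of the selected genes, 1208 were at the floor in the empty-vector library and 58 in the atp-2 RNAi library. By the size rule used here 1164 of them were 2-fold apart (1017 higher and 147 lower) and 608 were not. These 608 include 599 genes with under 1 FPKM in both libraries, which the rule could not count. That 0 had the opposite direction was fixed beforehand, since both ratios come from the same FPKM values. Among the selected genes reaching 10 FPKM in a library, 246 were higher and 100 lower. The authors' deposited table marks 409 of the selected genes as significant after adjustment, 407 higher and 2 lower, including 14 of the 51 sperm genes, 8 of the 121 collagen genes and 1 of the 6 vitellogenin genes. The authors' deposited table gives tbb-6 p = 0.00165 and q = 0.0607, vit-2 p = 0.051 and q = 0.403, and hsp-6 p = 0.989 and q = 0.993.

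**Figure D4:**
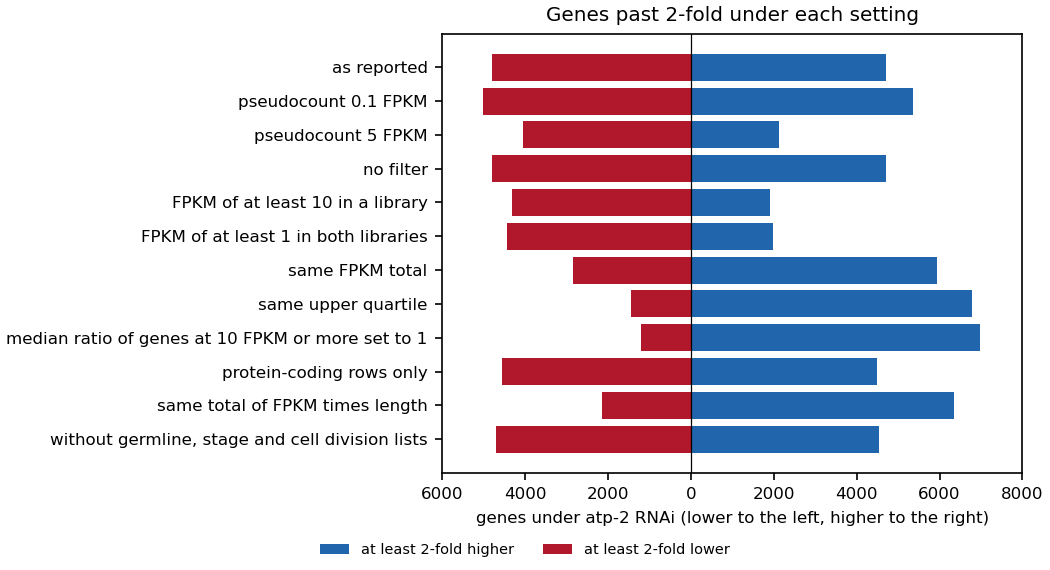
Number of genes at least 2-fold higher (bars to the right of 0) or lower (bars to the left) under atp-2 RNAi, 1 line per filter, pseudocount or scaling. As deposited 4697 genes were higher and 4787 lower, and with a median ratio of 1 for genes of at least 10 FPKM 6971 were higher and 1210 lower.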

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

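The scaling with equal totals of FPKM times length and the settings restricted to X-linked genes or leaving out the germline, stage and cell division lists were chosen after the results were seen. FPKM were scaled in a way not given in the sources used here, and with no counts and 1 library per group no setting measures error. Of 41 lists, 19 kept their side of the random range in every setting run, 12 of these also kept the sign of their median, and 10 lay outside the range in every setting: cytochrome P450, DAF-16 targets, proteasome, both neuropeptide lists, vitellogenins, collagens, cell division, oocyte and germline, and neurons. Over all lists and settings 23 medians moved out of the random range and 19 moved into it without a change of sign. A further 22 medians of lists outside it changed sign or side, and some of these also moved into it. The embryo list, too short for a range as deposited, lay below it with no filter. A further 28 medians, of 10 lists inside the range, changed sign, 23 of them under the 4 scalings. Of named genes past 2-fold 3 values changed sign, and of those within 2-fold 76 values of 22 genes, all under these scalings. Leaving out the filter added no gene past 2-fold, because the pseudocount keeps genes under 1 FPKM below 2-fold.

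The number of genes at least 2-fold higher was 2134 with a pseudocount of 5, 1918 with 10 FPKM in a library and 1991 with 1 FPKM in both, which remove or shrink genes of low FPKM. The number lower was 2832 with equal FPKM totals, 2144 with equal totals of FPKM times length, 1437 with equal upper quartiles and 1210 with a median ratio of 1, since each of these factors raises every atp-2 RNAi value. For the same reason atp-2 stood at -2.90, -2.68, -2.44 and -2.33 in that order. X-linked genes alone gave 695 higher and 371 lower, from fewer genes. All 1772 genes selected by the authors were 2-fold apart with no pseudocount and no filter, which their own 2-fold selection fixed beforehand.

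In the order equal FPKM totals, equal totals of FPKM times length, equal upper quartiles and median ratio of 1, the median turned positive for ATP synthase (0.49, 0.71, 0.96, 1.06), complexes I to IV (0.42, 0.64, 0.89, 0.99), tricarboxylic acid cycle (0.33, 0.55, 0.79, 0.90) and lysosome and autophagy genes (0.26, 0.48, 0.72, 0.83). With equal upper quartiles and a median ratio of 1 it did so for the mitochondrial ribosome (0.071 and 0.174) and for the peroxiredoxin gene prdx-2 (0.024 and 0.128), and with a median ratio of 1 for the germline helicase gene glh-1 (0.017). Against unmatched random lists the mitochondrial ribosome, at -1.01, lay below the random range and not above it. The cytosolic heat shock median was -0.69 with 10 FPKM in a library, -0.46 with 1 FPKM in both, and -0.69 over members of at least 10 FPKM, where the abundant members remain; the cause was not tested further.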

Other observations

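The tests of one scaling factor, of few fragments behind the germline, sperm and collagen lists, of somatic and neuronal shares, of chromosomes by level and of selected genes above 0 were chosen after the results were seen, as were the gene pairs and the genes named in the next 2 paragraphs.

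Gene pairs encoding versions of the same protein parted ways, and their ratio within a library is free of the scaling between libraries. The ATP synthase genes asb-1, known for its germline use, and asb-2 stood at a ratio of 3.92 in the empty-vector library and 0.307 in the atp-2 RNAi library. The complex I genes nduf-2.2 and gas-1 went from 2.74 to 0.305, the ribosomal protein genes rpl-11.1, also known for its germline use, and rpl-11.2 from 16.105 to 1.42, and rpl-25.2 and rpl-25.1 from 21.3 to 2.31. The glycolytic genes gpd-1 and gpd-2 went from 3.25 to 0.0507, and aldo-2 and aldo-1 from 20.4 to 0.658. These are log2 shifts of -3.67, -3.17, -3.51, -3.20, -6.001 and -4.95; gpd-2 shares much sequence with gpd-3, as does gpd-1 with gpd-4, so their values are uncertain.

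Of 6 measured ribosomal RNA genes, the 4 nuclear ones were at least 2-fold lower, with rrn-3.1 at 13283 and 1815 FPKM and rrn-2.1 at 12349 and 1367 FPKM. The mitochondrial MTCE.7 was 2-fold higher (551 and 1993 FPKM), MTCE.33 stood at 183 and 319.6 FPKM, and the share of all 6 in FPKM was 2.53% and 0.814%. Of 59 measured small nucleolar RNA genes, 41 were at least 2-fold lower and 9 higher, although their short length makes FPKM uncertain and the ribosomal RNA share can reflect how it was removed. Genes with large gains in level included the aspartic protease gene asp-6 (674 and 5773 FPKM) and the cadmium-responsive gene cdr-4 (96.2 and 2949 FPKM). Genes of developmental timing differed in direction, with lin-41 at 218 and 31.7 FPKM, lin-28 at 122 and 56.5 FPKM, lin-29 at 1.21 and 9.39 FPKM, lin-14 at 3.39 and 16.09 FPKM, and the adult collagen gene col-19 at 323 and 481 FPKM. By chromosome, the median log2 ratio was -0.76 on I, -0.17 on II, -0.75 on III, 0.15 on IV, 0.75 on V and 0.57 on X.

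Oocyte, yolk and cell division genes were lower while sperm and collagen genes were higher. One scaling factor moves every gene alike and cannot part the sperm and oocyte medians by 6.51 log2; few fragments would move lists of equal level alike, but the 29 oocyte and germline genes, all of at least 10 FPKM in both libraries, had a median of -3.03, and the lower quartiles of collagen and sperm genes lay 0.777 and 0.831 log2 above their matched random ranges. Among genes reaching 10 FPKM in a library the collagen and sperm medians were 3.61 and 3.99, with random lists up to 0.173 and 1.92. This filter can be met by the atp-2 RNAi library alone. With 1 FPKM required in both libraries, the 40 remaining collagen genes had a median of 1.15, with random lists up to -0.175. Only 5 sperm genes remained, with a median of 0.226 inside the random range. These values argue against few fragments as the cause for the oocyte and germline list and for collagens. For sperm genes few fragments stay open, since most were near 0 with empty vector. A smaller germline may account for the lower oocyte and cell division genes, but by itself would not raise sperm genes, which are also germline genes. A younger stage may account for the opposite directions of these lists. Both stay open. X-linked genes, which the germline uses little, lay 0.767 log2 above autosomal genes (0.57 against -0.19). Chromosome V lay higher still, and the X-linked median fell inside the range of random sets matched on expression (0.52 to 0.80). The test set beforehand counted a median inside that range against a smaller germline or younger stage. The difference depended on level, so that 1 median over all levels was a poor condition. At a mean of 30 to 300 FPKM the 282 X-linked genes had a median of 0.45 and each autosome lay between -1.52 and -1.26. At no other level did X-linked genes lie above each autosome. At 10 to 30 FPKM their median was -0.17, below IV (0.14) and V (0.63). At 300 FPKM or more it was -0.80, with autosomes from -0.83 to -0.60. Among genes under 10 FPKM, the most numerous, X-linked genes lay lower (0.79) than each autosome (1.105 to 1.23). The levels were compared after the results were seen and do not overturn the test. Timing genes went both ways, and stage, germline size and treatment cannot be told apart with 1 library each.

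Neuropeptide genes were higher in 70 of 79 cases. They were taken by name and include genes such as nlp-34 that are also in the antimicrobial list, so not all need be neuronal. The lower quartile of the neuropeptide genes lay 0.96 log2 above the upper quartile of the intestine list (1.64 against 0.67), and above that of body wall muscle (1.33). This argues only against a larger somatic share of the RNA that raised every somatic list alike. The quartiles of the pharynx list (1.60 to 2.39) and of collagens (1.54 to 4.12) overlapped those of the neuropeptide genes. A larger somatic share that raised some lists more than others stays open. A larger neuronal share remains open: the neuropeptide median (2.38) lay 0.34 log2 above the upper quartile of the neuron list (2.04), but the quartile ranges overlap, and several neuron markers are also used elsewhere. The vesicle genes ida-1 and sbt-1, at log2 ratios of 3.49 and 3.21, lay above the neuropeptide upper quartile (3.17), but the neuron genes snb-1, unc-33 and unc-119 stood at 0.19, -0.52 and -1.16. A change of peptide expression per neuron and a larger neuronal share cannot be told apart here.

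Of the genes in the authors' deposited table of selected genes, 89.9% were higher, against 49.5% of genes past 2-fold by size. These shares rest on unlike rules, since the authors' selection used no pseudocount, a lower FPKM minimum and a p-value. Among genes at least 8-fold apart by size, 703 were higher and 265 lower. Part of the difference came from genes at the floor. Of those at 0 in the empty-vector library and at least 0.3 FPKM in the other, 1208 of 1498 were selected, against 58 of 123 in the other direction. Of the 506 selected genes above 0 in both libraries 76.1% were still higher. Few fragments behind low values may contribute and stay open; 0.0835% of the 1197 selected genes with a length at 0 in the empty-vector library had values worth 3 fragments or fewer, but the minimum of 0.3 FPKM fixes this, as only 4.43% were short enough, and the unit is approximate. A selection favouring low FPKM stays open too: among genes 8-fold apart after the pseudocount, 50%, 34.02% and 40.8% of those of 1 to 10, 10 to 100 and at least 100 FPKM were selected, a ratio of 1.23 between the outer groups, which misses most genes of low FPKM. By the authors' own ratio, with no pseudocount, the shares at 0.3 to 1, 1 to 10, 10 to 100 and at least 100 FPKM were 53.6%, 38.6%, 27.1% and 39.8% over all genes, with no steady fall. In the same order the shares among genes above 0 in both libraries were 8.82%, 13.5%, 21.95% and 38.9%. These rose with FPKM, which argues against such a selection for the genes above 0 in both libraries only.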
